A study of Homo sapiens with 6 samples.

How the data were processed

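Total RNA extracted with Trizol from 6 cultures of BEAS-2B cells, 3 control and 3 treated with 50 µg/mL PM2.5 for 24 h, was labelled with biotin and hybridised to Affymetrix arrays, per the labels. The deposited values are log2 intensities, 1 per probe set and array, that the authors made with RMA, per the submitters' processing notes. RMA corrects background, normalizes by quantiles and summarises probes, which draws the arrays' distributions together. Its software, version and settings, and the genome build of the annotation, are not given in the sources used here. The highest deposited value, 19.9315, lies above the range of a 16-bit scanner, so the scale of the brightest probe sets is uncertain. The values were used as deposited, and the p-values rely on the replicates being biological, per the labels.

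The table held 70523 rows, of which 67528 were transcript clusters and 31 were Affymetrix control rows. The probe annotation of the platform gave 1 gene symbol to 23781 rows, several to 1543 and none to 45199. Symbols were updated through gene identifiers against RefSeq genes of the GRCh38.p14 annotation, which served for names, biotypes and, in 1 test, gene span only: 21497 rows matched by gene identifier, 1974 by a current symbol and 306 by an older symbol, and 4 kept an unmatched symbol. Rows with several symbols or none, and control rows, were left out of the gene tests. The lowest 30% of the remaining rows by mean over the 6 arrays were left out, and each gene was represented by its row with the highest mean, which left 15785 genes. Of these, 63 had the same value on every array within 0.005, and 41 lay at the highest value on all arrays of a group. A flat gene gives no information on a difference, and a gene at the highest value in 1 group gives only a lower bound of it. The 23 antigenomic background probe sets ranged from 3.3 to 5.59, with a median of 3.81, and many genes lay in that range, where differences are compressed.

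The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend of the prior variance on the mean, two-sided), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. A set of 38 gene lists was tested with camera (preset correlation 0.01), beside camera with an estimated correlation and fry, with adjustment over the 37 lists that had at least 4 measured genes. Of the 9 lists with a camera call, none held with an estimated correlation. With 6 arrays that test rests on 4 residual degrees of freedom, where the preset test rests on a number near that of the genes. A call lost there may reflect this low power and not correlation between members. The fry test, which asks whether the genes of a list move one way, gave an adjusted p below 0.05 for 3 of them. These were aryl hydrocarbon receptor targets (0.0257), NF-kB feedback and surface targets (0.0182) and immediate early genes (0.0257). Figures were drawn with matplotlib 3.10.9. The groups, tests, lists, most alternative settings and the rule for naming genes were set before the data were examined. The rule named the genes with the largest changes among those that passed or, with fewer than 5 in a direction, the 6 with the smallest p; a fixed set of 18 genes, 1 of which is not reported here; members of the lists that passed; and, for lists with a camera call, members with the largest differences.

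Alternative settings changed the filter, the probe set that stands for a gene, the normalization, the variance prior, the weights of the arrays, a block for the replicate number, the threshold and each array left out. Chosen after seeing the data were the median snoRNA level as a covariate, protein-coding genes alone, genes that are not flat, and the called lists without control replicate 3 with an estimated correlation. The procedure was tested on simulated data with the means and residual SDs of the 15785 genes and independent normal errors. With 6 arrays it recovered 25 of 50 genes changed by 0.5 on the log2 scale, 34 of 50 changed by 1, 43 of 50 changed by 2 and 48 of 50 changed by 4, with 10 false calls. Real errors are correlated between genes, which this simulation leaves out. It also spreads the residual of a gene evenly over the arrays, while in the data control replicate 3 lay apart from the other controls in many genes at once. The recovery therefore does not give the power of the real comparison.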

Results

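Gene expression was measured in BEAS-2B cells, an established line of human bronchial epithelial cells, on 6 whole-transcript microarrays. Cells had 24 h to attach and were then kept for 24 h in DMEM alone (control, 3 arrays) or in DMEM with 50 µg/mL of suspended fine particulate matter (PM2.5, 3 arrays). The labels call the 3 replicates of each group biological. Array medians over all deposited rows were 4.18, 4.14 and 4.04 on the log2 scale for control replicates 1 to 3 and 4.07, 4.12 and 4.12 for PM2.5 replicates 1 to 3. The number of arrays limits the precision of every value. All differences are PM2.5 minus control on the log2 scale.

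The comparison asks which transcripts differ between exposed and unexposed cells. Among the genes named here, *SECTM1*, *SLC7A5*, *CYP1B1* and *EGR1* lay higher and *DKK1* lower on all PM2.5 arrays than on all control arrays. *DKK1*, which encodes a secreted inhibitor of Wnt signalling, had a log2 value of 10.35 ± 0.28 (SD, n = 3) in control and 7.58 ± 0.24 (SD, n = 3) in PM2.5. *SECTM1*, which encodes a transmembrane and secreted protein, had 6.17 ± 0.27 (SD, n = 3) in control and 8.68 ± 0.16 (SD, n = 3) in PM2.5. As groups, target genes of the aryl hydrocarbon receptor, of NF-kB and of immediate early signalling lay higher in PM2.5 than other genes, and mitotic genes lay lower, in a test that presets the correlation between genes. None of these group calls held with an estimated correlation (adjusted p = 0.437, 0.244, 0.244 and 0.885 in that order), and the mitotic call ended without control replicate 3 (adjusted p = 0.74). In fry the adjusted p was 0.0257, 0.0182, 0.0257 and 0.612 in the same order. No single gene passed the test over all genes with 6 arrays of equal weight and a trended variance prior.

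Of 15785 genes tested with limma, 0 were higher and 0 were lower at an adjusted p below 0.05, so 0 changed at least 2-fold by that test. The smallest adjusted p was 0.111. At an unadjusted p below 0.05 there were 2663 genes, 1041 of them higher and 1622 lower in PM2.5, where chance gives 789. In 3629 genes (23% of those tested, against 10% by chance) the 3 arrays of one group all lay above those of the other, and 299 of these differed at least 2-fold, 109 higher and 190 lower in PM2.5. Control replicate 3 decided the count of calls: without it limma gave 484 genes higher and 734 lower, 556 of them at least 2-fold apart. Among protein-coding genes these calls were 470 higher and 283 lower. In 71.3% of the 1218 calls control replicate 3 lay nearer to PM2.5 than to the other controls, so most of them do not separate exposed from unexposed arrays. It lay under 0.25 of the way from the other controls to PM2.5 in 199 calls, and in 33 of those at least 2-fold apart.

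Control replicate 3 stood apart from the other controls. Over the tested genes it correlated with control replicates 1 and 2 at r = 0.95 and 0.962 and with the PM2.5 arrays at 0.987, 0.977 and 0.981, across genes that are not independent replicates. Control replicates 1 and 2 correlated at 0.991, and the PM2.5 arrays among themselves at 0.992 to 0.995. In control replicate 3, 8.01% of genes lay over 2-fold from the other arrays of the group, against 4.33% and 2.03% in control replicates 1 and 2 and at most 0.481% on a PM2.5 array. Small nucleolar RNAs, which guide the modification of other RNAs, showed the same split. The median of 221 snoRNA genes was 9.25 and 9.07 in control replicates 1 and 2, 7.1 in control replicate 3, and 6.95, 6.9 and 6.78 in PM2.5 replicates 1 to 3.

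**Figure D1:**
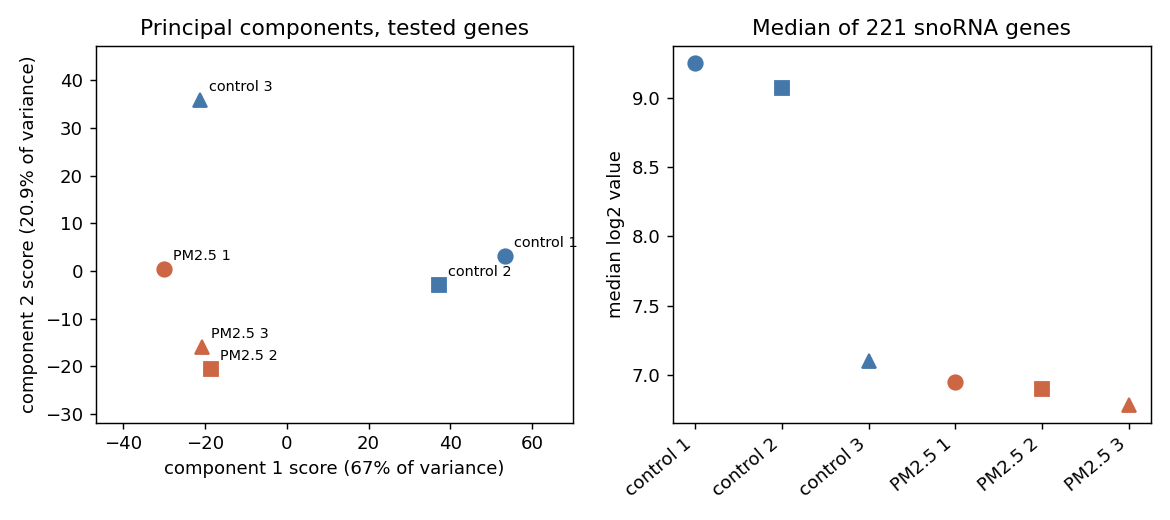
Left, scores of the 6 arrays on the first principal components of the tested genes, which hold 67% and 20.9% of the variance; right, the median log2 value of 221 snoRNA genes on each array, with controls in blue and PM2.5 in orange. Control replicates 1 and 2 lie at 53.31 and 37.17 on component 1 and control replicate 3 at -21.15, among the PM2.5 arrays, which lie between -30.05 and -18.51, while on component 2 it lies apart from them, at 35.91 against -20.54 to 0.32.

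The 6 genes with the smallest p in each direction are named here although none passed that test over all genes with 6 arrays. The higher ones were *SECTM1* (difference 2.51, SE 0.201), *SEMA6B* (0.60, SE 0.0552), which encodes a semaphorin, *SLC37A2* (0.70, SE 0.0672), *ALDH3A1* (0.45, SE 0.0438), an aldehyde dehydrogenase, *MUC1* (0.60, SE 0.0604), a membrane mucin, and the transcript cluster annotated to *MIR297* (1.60, SE 0.161). The lower ones were *MRPS23* (-1.34, SE 0.118), a protein of the mitochondrial ribosome, *DKK1* (-2.76, SE 0.254), *ZNF431* (-0.59, SE 0.0597), the transcript cluster annotated to *MIR548AC* (-1.86, SE 0.199), the mitotic kinesin gene *KIF20B* (-0.53, SE 0.057) and *SUB1* (-0.61, SE 0.0711). In limma their adjusted p values were 0.111 or 0.112, and in each of them the 3 PM2.5 arrays lay on one side of the 3 controls. Without control replicate 3 all 12 passed, from 0.00652 for *SECTM1* to 0.0199 for *SUB1*. A second cluster annotated to *MIR548AC* differed by -0.34. *ALDH3A1* (4.26 in control), *SLC37A2* (4.37) and *ZNF431* (4.5 in PM2.5) lay within the range of the antigenomic background probe sets, 3.3 to 5.59, and so did *SEMA6B*, *MUC1*, *MIR297*, *KIF20B* and *SUB1* in at least one group.

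**Figure D2:**
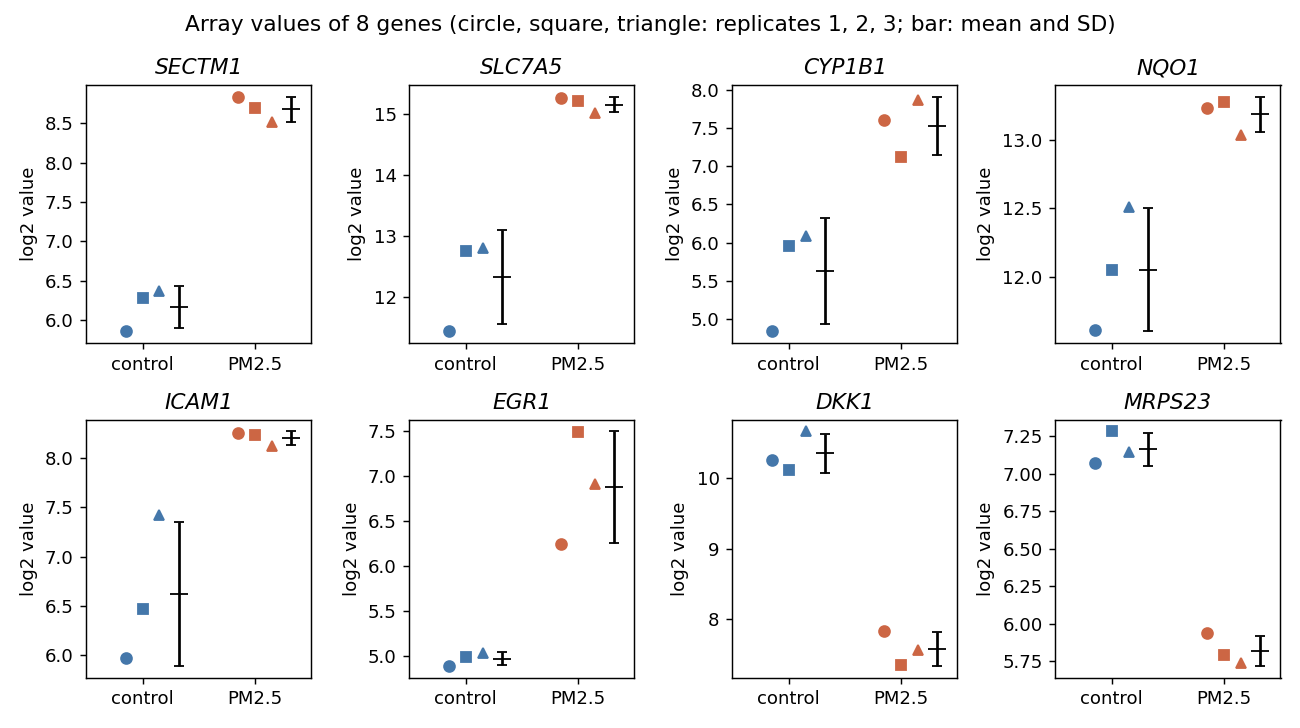
Log2 values of 8 genes on each array, with controls in blue, PM2.5 in orange, replicates 1 to 3 as circle, square and triangle, and the mean with its SD beside each group; axes do not start at 0. In *SECTM1* the controls lie between 5.86 and 6.37 and the PM2.5 arrays between 8.52 and 8.83, and in *ICAM1* control replicate 3, at 7.42, lies closer to the PM2.5 arrays than control replicate 1, at 5.97.

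Aryl hydrocarbon receptor targets lay higher in PM2.5 in camera (adjusted p = 1.85e-06) and in fry (adjusted p = 0.0257). In camera with an estimated correlation the call for targets of the receptor was lost (adjusted p = 0.437). This receptor binds polycyclic aromatic hydrocarbons and drives genes of xenobiotic metabolism. Of 12 measured members, 10 were higher and 2 lower, with a median difference of 0.50. None passed over all genes, and 7 passed adjusted over the list alone, all of them higher. *SLC7A5*, an amino acid transporter gene, went from 12.33 ± 0.77 to 15.16 ± 0.13 (SD, n = 3 each), a difference of 2.83 (SE 0.387). *CYP1B1*, a cytochrome P450 gene that the receptor induces, went from 5.63 ± 0.69 to 7.53 ± 0.38 (SD, n = 3 each), a difference of 1.90 (SE 0.387), and its second transcript cluster differed by 1.93. *NQO1* differed by 1.13 (SE 0.264) and *TNFAIP2* by 1.12 (SE 0.244). In *TIPARP* the groups overlapped, with a difference of 0.05. *CYP1A1* lay below the filter on dim probe sets, at 3.7 ± 0.12 in control and 3.88 ± 0.08 in PM2.5 (SD, n = 3 each), within the background range. *AHRR* and *SRXN1* had no probe set annotated to that gene alone and are not analysed here. Control replicate 3 moved with this list, at a median of 0.27 over the other controls.

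NF-kB feedback and surface targets also lay higher, 14 of 17 measured members, with a median of 0.36. Of these, 6 passed adjusted over the list alone and none over all genes. *ICAM1*, an adhesion molecule gene, differed by 1.58 (SE 0.377), *TNIP1*, an inhibitor of the pathway, by 1.35 (SE 0.287), and *NFKBIA* by 0.76 (SE 0.408) with overlapping groups. The median of control replicate 3 was 0.17 over the other controls. The adjusted p was 2.85e-05 in camera, 0.0182 in fry and 0.244 in camera with an estimated correlation. The estimate itself was 0.0112, close to the preset 0.01, so a higher correlation between members does not account for the lost call. Among inflammatory cytokines and chemokines, 12 of 17 were higher and 5 lower, with a median of 0.13, and 6 passed adjusted over the list alone, 5 higher and 1 lower. *CXCL1* differed by 0.95 (SE 0.202), *CSF1* by 0.54 (SE 0.102) and *IL6* by 0.34 (SE 0.0696), with no overlap between groups. *IL6*, at 4.76 in control and 5.1 in PM2.5, lay within the antigenomic background range of 3.3 to 5.59, where a difference is compressed. *CSF1* did so in control, at 5.26. The groups overlapped in *CXCL8* (0.02, SE 0.514), *IL1B* (0.33, SE 0.196), *CCL2* (0.70, SE 0.597) and *IL18* (-0.90, SE 0.458). The adjusted p of this list was 0.0284 in camera, 0.675 with an estimated correlation, 0.0549 and 0.0633 without control replicates 2 and 3, and 0.0803 without PM2.5 replicate 2.

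Immediate early genes, which respond within minutes to growth factors and stress, were higher in 17 of 24 measured members, with a median of 0.07, or 0.13 without control replicate 3. Adjusted over the list alone, 4 passed: *EGR1*, *JUNB* and, named after their values were seen, *FOSL1* and *ZFP36*. *EGR1*, a zinc finger transcription factor gene, went from 4.97 ± 0.07 to 6.88 ± 0.62 (SD, n = 3 each), *JUNB* differed by 0.89 (SE 0.149), *IER3* by 1.41 (SE 0.396) and *KLF2* by 0.79 (SE 0.276), the last pair not passing over the list alone. The 6 probe sets of *IER3* gave differences of 1.20 to 1.41. *ATF3* differed by -0.06 with overlapping groups. In control *EGR1*, at 4.97, and *JUNB*, at 5.14, lay within the antigenomic background range of 3.3 to 5.59, where a difference is compressed. The adjusted p was 0.0016 in camera, 0.0257 in fry and 0.244 in camera with an estimated correlation. That estimate was -0.0192, below the preset 0.01, so a higher correlation between members does not account for the lost call.

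Lists of metabolism and metal response also lay higher in camera. Glycolysis enzymes were higher in 14 of 16 members, with a median of 0.16, and the other 2, *GAPDH* and *ENO1*, had the same value on every array. *GPI* differed by 1.51 (SE 0.385), *ALDOC* by 0.88, and *PGAM1* and *PGK1* by 1.08 and 0.98 with overlapping groups. Lysosome and autophagy genes were higher in 18 of 23 members, with a median of 0.13: *ATG9A* differed by 0.77 (SE 0.218), the protease gene *CTSD* by 0.74 (SE 0.232), the autophagy receptor gene *SQSTM1* by 0.55 (SE 0.191) and *NPC1* by 1.01 (SE 0.535) with overlap. Metallothioneins and zinc response genes, which include metal-binding proteins, were higher in 10 of 11, with a median of 0.18 and 1 flat gene. *MT1F* differed by 1.11 (SE 0.31), *MT1M* by 0.32, *MT1X* by 0.20 and *MT1B* by 0.19. None of the members of these lists passed adjusted over the list alone. The camera adjusted p values were 0.00486, 0.0112 and 0.0284, and the adjusted p was 0.799 for each with an estimated correlation. In control replicate 3 the medians of the glycolysis, lysosome and metallothionein lists were 0.32, 0.45 and 0.27 over the other controls, and without this array the median differences were 0.29, 0.38 and 0.27. Against control replicate 3 alone the medians of PM2.5 were 0.02, -0.15 and 0 in that order, so these lists lay higher only against the other controls. *PGK1* and *NPC1* passed over all genes without control replicate 3, at 1.514 (adjusted p = 0.0468) and 1.596 (adjusted p = 0.0351). The adjusted p of the lysosome list was 0.138 without control replicate 1, and that of the metallothionein list was 0.0636 and 0.0955 without control replicates 1 and 2 and 0.0803 without PM2.5 replicate 2.

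Mitotic genes and ribosomal proteins lay lower in the camera test, and both calls ended without control replicate 3. Of 36 cell cycle G2/M and mitosis genes 28 were lower, with a median of -0.25, and 1 passed adjusted over the list alone, *ASPM*, named after its values were seen. *ANLN* differed by -1.34 (SE 0.354), *TTK* by -1.03 (SE 0.323) and *TOP2A* by -0.94 (SE 0.3), while *KIF20A* differed by 0.85 (SE 0.796) in the other direction, with overlap. For *KIF20A* the difference was 0.275 without control replicate 1, 0.519 without control replicate 2 and 1.746 (adjusted p = 0.0414) without control replicate 3. The adjusted p was 0.0103 in camera, 0.885 with an estimated correlation and 0.74 without control replicate 3, where the median was -0.10. The median of this list was 0.73 higher in control replicate 3 than in the other controls. Cytosolic ribosomal proteins were lower in 23 of 33 members, higher in 5 and flat in 5, with a median of -0.11, and none passed adjusted over the list alone. *RPL14* differed by -1.44 (SE 0.276), *RPL24* by -0.65 (SE 0.207), *RPS25* by -1.12 and *RPL10A* by -0.67, the last pair with overlap. The adjusted p was 0.0284 in camera, 0.799 with an estimated correlation, 0.256 without control replicate 3, and 0.0803 and 0.0679 without PM2.5 replicates 2 and 3.

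**Figure D3:**
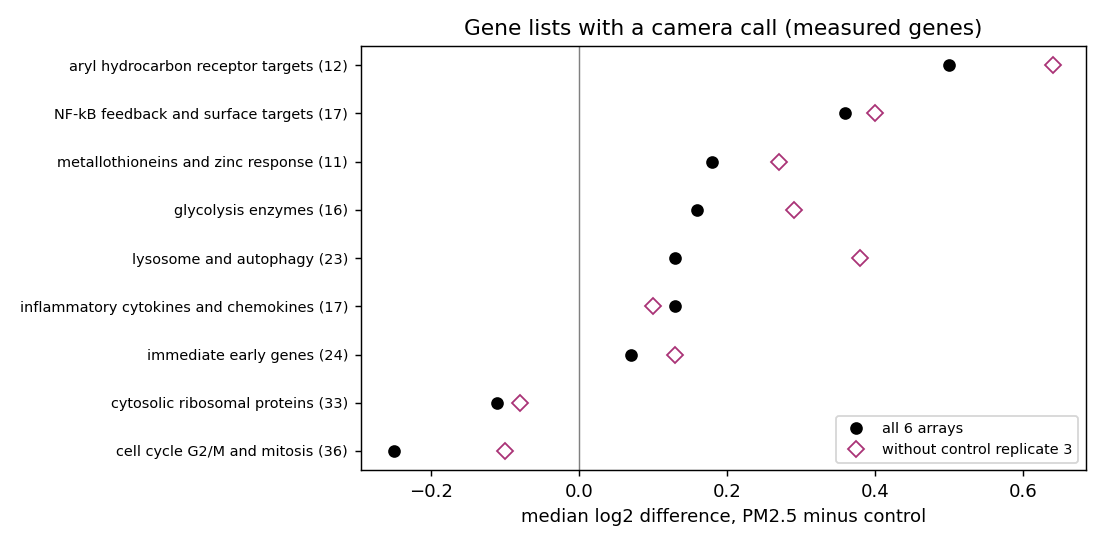
Median log2 difference, PM2.5 minus control, of the 9 gene lists with a camera adjusted p below 0.05, with the number of measured genes in brackets; filled circles use all 6 arrays and open diamonds leave out control replicate 3. Aryl hydrocarbon receptor targets lie highest, at 0.50 and 0.64, and mitotic genes lowest with 6 arrays, at -0.25, against -0.10 without control replicate 3.

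NRF2 antioxidant targets gave no camera call (adjusted p = 0.385, median 0.01): 14 of 25 were higher, 10 lower and 1 flat, and 3 passed adjusted over the list alone, 2 higher and 1 lower. Apart from *NQO1*, the antioxidant genes named in advance overlapped between groups, *HMOX1* at 0.06, *GCLM* at 0.05 and *TXNRD1* at 0.15. The groups also overlapped in *CDKN1A* at 0.15, *DDIT3* at -0.06 and *HSPA1A* at 0.54. *HMOX1* and *GCLM* lay within the background range of 3.3 to 5.59 in both groups, where a difference is compressed, and so did *DDIT3*, *ATF3* and *TIPARP*. *HSPA1A* was read from a probe set on an alternative haplotype, and its 4 probe sets gave 0.52 to 0.54.

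The other tested pathway lists gave no camera call. Oxidative phosphorylation subunits had an adjusted p of 0.0616 and a median of -0.25, DNA double-strand break and replication stress repair 0.0718 and -0.07, fatty acid synthesis and desaturation 0.112 and 0.18, cell cycle G1/S and DNA replication 0.113 and 0.19, ribosome biogenesis 0.179 and -0.10, and replication-dependent histones 0.202 and -0.14. Hypoxia and HIF targets had 0.27 and 0.01, glucocorticoid receptor targets 0.27 and 0.10, p53 targets 0.281 and -0.07, peroxisome proliferator-activated receptor and lipid storage genes 0.348 and 0.03, heat shock response 0.515 and -0.12, and TGF-beta targets 0.538 and -0.07. The ATF4 integrated stress response had an adjusted p of 0.637 and a median of -0.04, interferon-stimulated genes 0.637 and 0.00, squamous differentiation 0.653 and -0.05, the unfolded protein response 0.658 and 0.03, extracellular matrix and mesenchymal genes 0.658 and 0.00, and matrix metalloproteases and inhibitors 0.658 and -0.03. Cholesterol biosynthesis and uptake had 0.698 and -0.06, the circadian clock 0.865 and -0.02, epithelial junction genes 0.887 and -0.04, and apoptosis regulators 0.992 and 0.04. The ATF4 and matrix metalloprotease lists had a negative median, a mean of 0.07 and 0.22 and a test direction of up, and apoptosis regulators had a positive median, a mean of -0.01 and a test direction of up. Adjusted over the list alone, 4 genes passed in the ATF4 list, 3 in the hypoxia list, 2 each in the unfolded protein, glucocorticoid, double-strand break, TGF-beta and oxidative phosphorylation lists and 1 each in the p53, extracellular matrix and matrix metalloprotease lists, and none over all genes. Without control replicate 3 the camera adjusted p was 0.00014 for the G1/S list, 0.0226 for fatty acid synthesis and 0.0294 for hypoxia, all with direction up, and the adjusted p was 0.742, 0.742 and 0.696 with an estimated correlation. The medians of these lists in control replicate 3 were 0.61, 0.25 and 0.29 over the other controls.

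Markers of other cell types did not move as groups. The camera adjusted p was 0.385 for macrophage and leukocyte markers (median 0.04), 0.865 for airway basal cell markers (-0.03) and fibroblast markers (0.00), 0.954 for endothelial markers (-0.04) and 1 for airway ciliated cell markers (-0.01). The basal list had a mean of 0.09 and a test direction of up, and the endothelial list a mean of 0.11 and a test direction of down. Adjusted over the list alone, 1 gene was higher in the macrophage list, and 1 was higher and 1 lower in the basal list. Of the airway club and goblet cell markers 2 were measured, too few for a test, with a median of -0.05.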

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

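The snoRNA covariate, protein-coding genes alone, flat genes left out and the estimated correlation without control replicate 3 were alternatives chosen after seeing the data. The counts of 0 genes higher, 0 lower and 0 changed at least 2-fold in limma (2663 at an unadjusted p below 0.05) were the same under 12 of the 14 settings that kept all arrays, with a smallest adjusted p between 0.0502 (quantile normalization) and 0.35 (replicate block). The stricter threshold of 0.01 was among these 12, and it could give no calls where 0.05 gave none. With trend=FALSE 4 genes were higher (*SECTM1*, *SEMA6B*, *MAP3K11* and *VEGFA*), 3 lower (*DKK1*, *MRPS23* and *RPP21*) and 3 changed at least 2-fold, each at an adjusted p of 0.0412. With array weights, which gave control replicates 1 to 3 weights of 0.53, 4.88 and 0.2, 1225 were higher, 1987 lower and 622 changed at least 2-fold. Leaving out 1 array at a time gave 0 to 484 genes higher, 0 to 734 lower and 0 to 556 changed at least 2-fold, and the calls came only from leaving out control replicate 3. The cause was not tested. Deviations of arrays with the same replicate number correlated at -0.43, 0.42 and -0.2. These values cannot decide whether the numbers pair the arrays, as deviations within a group sum to 0 and are not independent. The replicate block gave 0 calls, as did the fit without it.

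Array weights turned *TIPARP* to -0.025 and *HMOX1* to 0, and quantile normalization turned *ATF3* to 0.002. The snoRNA level as a covariate turned *GCLM* to -0.028, *TXNRD1* to -0.312, *CXCL8* to -0.73, *IL1B* to -0.062, *HSPA1A* to -0.233, *CCL2* to -0.381, *NFKBIA* to -0.083, *PGAM1* to -0.304, *PGK1* to -0.289, *KIF20A* to -1.224 and *NPC1* to -0.316. It kept the sign but moved *ICAM1* to 0.644, *NQO1* to 0.602, *CXCL1* to 0.55, *TNFAIP2* to 0.693, *MT1F* to 0.683 and *IL18* to -1.961, among others. Leaving out 1 array at a time gave -0.035 to 0.099 for *TIPARP*, -0.012 to 0.086 for *GCLM* and -0.507 to 0.387 for *CXCL8*. It gave 0.015 to 0.102 for *HMOX1*, -0.083 to -0.035 for *DDIT3* and -0.086 to -0.036 for *ATF3*. Without a change of sign it gave 0.518 to 1.674 for *PGAM1*, 0.501 to 1.514 for *PGK1*, 0.504 to 1.075 for *ALDOC*, 0.643 to 1.596 for *NPC1*, 0.275 to 1.746 for *KIF20A*, 0.272 to 1.21 for *CCL2*, -1.244 to -0.44 for *IL18*, 0.355 to 1.106 for *NFKBIA*, 0.104 to 0.859 for *HSPA1A*, 0.187 to 0.507 for *IL1B*, -1.443 to -0.633 for *RPS25*, 0.184 to 0.443 for *MT1M*, 0.124 to 0.233 for *MT1B*, 0.074 to 0.267 for *CDKN1A* and 0.044 to 0.358 for *TXNRD1*. None of these genes passed the test of the report, and the cause of the turns was not tested. Genes that passed as higher with array weights included *IL1B* (adjusted p = 0.0346), *PGK1* (0.0302), *KIF20A* (0.0467), *NPC1* (0.0214), *ICAM1* (0.0101), *NQO1* (0.0106), *CXCL1* (0.0102), *TNFAIP2* (0.0108) and *MT1F* (0.0367). With an estimated correlation none of the 9 list calls was kept, with or without control replicate 3. The replicate block ended the call of the ribosomal protein list (adjusted p = 0.0677), and no filter that of the cytokine list (0.0766). The array held no 3' and 5' control probe sets for *GAPDH* and *ACTB*, so that comparison was not run. Signal over background limits genes near the background range of 3.3 to 5.59.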

Other observations

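The tests of explanations and of splits in this part were chosen after the values were seen, except the test of gene span, whose outcome was written down first; the setting without control replicate 3 was chosen beforehand, and the genes named here were also chosen after their values were seen. In 16 genes control replicate 3 lay within 0.5 of the mean of the other controls while all PM2.5 arrays lay at least 2-fold from that mean, 10 of them higher and 6 lower in PM2.5. *SHISA2* had 4.84, 4.85 and 5.04 in the controls and 9.67, 8.01 and 8.74 in PM2.5. *STC2*, which encodes a secreted glycoprotein, differed by 1.51, the Wnt co-receptor gene *LRP5* by 1.24, and the cyclin-dependent kinase regulator gene *CKS2* by -2.29. None of these 4 passed with 6 arrays of equal weight and a trended variance prior. Of the replication-dependent histones measured, 5 were lower in PM2.5 and 2 had the same value on every array, and fry gave an adjusted p of 0.0185 without the flat genes, where camera gave 0.113.

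Without control replicate 3, 135 of the 734 lower calls (18.4%) were short RNA genes (snoRNA, snRNA, vault, Y and other small noncoding RNA, miRNA not counted), which are 1.74% of the genes tested, against 0 of the 484 higher calls. Among the 1218 genes called, control replicate 3 lay nearer to PM2.5 than to the other controls in 71.3%. The 4 vault RNAs had medians of 10.95 and 10.34 in control replicates 1 and 2, 6.94 in control replicate 3 and 6.93 to 7.14 in PM2.5.

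Control replicate 3 lies apart from the other controls. It kept the control level in 16 genes where a PM2.5 array put in its place did so in at most 4. This argues against a mislabelled array that is exchangeable with the PM2.5 arrays. It cannot decide on a treated culture handled apart from them, since any array outside their close cluster could exceed that count. Treated RNA mixed into this sample stays open. A mixture lies between its sources, and control replicate 3 lay above all other arrays in 27 of 36 mitotic genes, against at most 6 for another array. That list was chosen because control replicate 3 stood furthest apart there. It lay at least 2-fold outside all others in 85 protein-coding genes, but control replicate 1 did so in 113, so this count does not decide. The culture of control replicate 3 could have differed too. 2 earlier forms of this test did not decide either. In the first, 3.38% of genes had a mixing share under 0.1 and 55.4% over 0.9, with a median of 0.96. In the second, the best mixture had a share of 0.93. From it 42.6% of 68 genes lay over 0.5 away, where the bound set could not be reached. Of the same genes, 50%, 19.1% and 10.3% lay over 0.5 from the mean of the other PM2.5 arrays in PM2.5 replicates 1 to 3. Shares this near 1 stand beside the 16 genes that kept the control level. A lower recovery of short RNA is in line with a median of -1.17 for short RNA genes against the other controls, beside 0.03 for protein-coding genes, -0.25 for the snRNA genes among them and -0.2 for miRNA genes, and it is not the whole pattern, since 513 protein-coding genes lay at least 2-fold from the mean of the other controls where these were within 0.5 of each other, against at most 26 on a PM2.5 array and 59 in control replicate 1. For the short RNA of control replicate 3, which lay nearer to PM2.5 in 74.8% of short RNA genes, exposure stays open. The label calls this sample a control, but whether the label holds is in question here, so it cannot decide. RNA of exposed cells, if mixed in, would have to make up nearly all of this sample, against the 16 genes at control level. Those genes were picked for lying at that level, and a weaker or shorter exposure of this culture was not tested. For the PM2.5 arrays exposure and recovery cannot be told apart, as the median of these genes there lay -1.09 from control replicates 1 and 2 and -0.01 from control replicate 3.

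The 4 poly-A spike-ins, added to RNA before labelling, were lower on every PM2.5 array than on every control array, with a mean difference of -0.95. A weaker hybridization is argued against by the hybridization spike-ins, which differed by 0.04 on average. The amount of spike-in, the amount of RNA and a labelling batch that follows the groups cannot be told apart, as the labels give no batch and the poly-A difference of -0.95 follows the groups. Such a batch could also shift the gene and list differences of this report, and this was not tested. An exact permutation test of 3 arrays against 3 cannot give a two-sided p below 0.1.

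Mitochondrial ribosomal protein genes may be lower in PM2.5, as a hypothesis taken from *MRPS23* and *MRPL50*. Of 71 such genes, 54 were lower, with a median of -0.16, and 2 passed adjusted over the list alone. None of 10000 random lists matched on gene span and mean expression had a median as low (0%). Such lists ignore the correlation between genes, and the tested genes include *MRPS23*, which prompted the hypothesis. The unadjusted p was 0.000706 in camera with the preset, 0.319 in camera with an estimated correlation and 0.151 in fry. Part or most of the difference may come from control replicate 3. In these genes its median was 0.29 over the other controls, and PM2.5 lay at a median of -0.46 from it. Without this array the median difference was -0.07 for these genes and -0.09 for the oxidative phosphorylation list, where it was -0.25 with all arrays. The bounds first set for those medians differed between the lists and gave opposite readings of these nearly equal values, so 1 bound was set for both after they were seen, and it leaves both open.

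The 6 arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. All 10 splits gave 0 genes at an adjusted p below 0.05 in limma, the highest of the other splits included. At an unadjusted p below 0.05 the real split gave 2663 genes, as many as no other (1 of 10), and the highest other gave 2045. Among 27353 rows without a single gene symbol that were above the filter on dim probe sets, 1 passed limma with an adjusted p of 0.00587, a probe set with no gene name in the annotation, at 19.13, 19.17 and 19.01 in control and 16.72, 16.68 and 16.5 in PM2.5, values above a 16-bit scale.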
